A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

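RNA cross-linked to protein was measured by CRAC (UV cross-linking followed by affinity purification of a tagged protein, and sequencing of the cDNA of the RNA that stays attached) in 4 libraries of the fission yeast Schizosaccharomyces pombe. Per the labels' protocols, cells grew at 30 °C in rich medium and were irradiated for 3 min before harvest. There were 2 libraries from a strain carrying HTP-tagged Seb1, an RNA-binding protein related to budding yeast Nrd1, and 2 from the untagged parental strain, which give the background of the purification. The series design calls the 2 libraries of each group biological replicates.

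The deposited files hold read counts: each record is a mapped interval with the number of reads it stands for, its strand, the annotated features it overlaps, and the positions of substitutions and deletions. Per the file headers, they were written by Counters 1.4.2. Per the submitters' processing notes, alignment used Novoalign 2.0.4 and the S. pombe build ASM294v2. The records, however, lie on the 16 nuclear chromosomes and the mitochondrial genome of the budding yeast Saccharomyces cerevisiae and carry the names of S. cerevisiae genes. The release of that genome, and the reason for placing S. pombe reads on it, are not given in the sources used here. Each value below therefore describes S. pombe library reads that could be placed on S. cerevisiae sequence, at S. cerevisiae positions as the files give them, and a gene name stands for the S. cerevisiae feature. The S. pombe reference supplied for this work was not used for positions or names.

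Header totals were checked against the records: in each library the reads over all records equalled single reads plus 1 per read pair. The share of raw reads that mapped was 18.6% and 33.6% in the untagged controls and 12.5% and 8.91% in the Seb1-HTP libraries. Records that name no feature (1.61% and 0.334% of control reads, 2.12% and 4.90% of Seb1-HTP reads) were left out of library totals and tests. Records list overlapping features on either strand, so a read was counted for a feature only where its record named that feature alone: 8.06% and 4.25% of named reads in the controls, 15.6% and 19.3% in the Seb1-HTP libraries. Most of the rest name several features of the 35S rDNA. The adapters hold random bases, per the labels' protocols, and whether repeated reads were collapsed is not given in the sources used here. Intervals and floors therefore cover counting error only. An interval is the 95% Wilson interval unless named otherwise, and a count of 0 is read against a floor of 3 reads, worth 655 and 66.2 reads per 1000000 named reads (RPM) in the controls and 11.2 and 13.0 in the Seb1-HTP libraries.

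Gene-level differences were tested with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) on the deposited counts with library totals as scaling, for features with at least 10 reads over the 4 libraries, and Benjamini-Hochberg adjustment at 0.05. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 3 members were tested. Their S. pombe symbols were matched to S. cerevisiae names by spelling (ribosomal proteins, snoRNAs, tRNAs and rRNAs by name pattern, mitochondrial features by chromosome or name), so a match need not be the ortholog. Shares were compared by exact two-sided permutation tests, which with 2 against 2 libraries cannot go below p = 0.333. Named genes follow a rule fixed beforehand: the 8 with the smallest p called in each direction, the 6 protein-coding and 4 non-coding genes with the highest mean RPM in Seb1-HTP, the tagged gene, and the 3 tested members of each list with the smallest p. No feature named after seb1 was met. The shares of 25S, 5.8S and 18S rRNA, the tests along the 35S rDNA in 250-nt windows, those by strand and read length, and frames without RRT15 and YLR162W were added after seeing the data. Reads of the 2 rDNA copies cannot be told apart where the copies match, so windows of the copies are not independent.

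The scripts were tested on simulated data. With the spread of these libraries (dispersion 1.83), the gene test, run on 392 of 559 simulated features after the filter, recovered 0% of features changed 64-fold in either direction. With a dispersion of 0.1 it recovered 97.0% of those 16-fold lower and 17.6% of those 16-fold higher in Seb1-HTP. For the 49 rDNA windows (dispersion 0.365), it recovered 3 of 3 windows 16-fold lower and 1 of 3 windows 16-fold higher. Alternatives were TMM factors, DESeq2 1.42.0, totals without rRNA and tRNA, other filters, reads counted for each feature named, distinct fragments (each chromosome, start, end and strand once, with the differences of its first record), thinning to the deeper control over 20 draws, the replicate number as a block, and each library left out. Read positions along genes and UGUA motif content were not analysed here, since both need the S. cerevisiae genome and annotation. Other values used Python 3.11.15 with scipy 1.17.1.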

Results

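The 4 libraries differed widely in depth. Untagged controls 1 and 2 held 4579 and 45339 reads naming at least 1 feature, and Seb1-HTP libraries 1 and 2 held 268030 and 231656, from 35034, 202528, 3452998 and 3946246 raw reads. As distinct intervals, named or not, these were 1013, 3805, 17599 and 42786 fragments. Control 1 is the shallowest, and its 3-read floor of 0.0655% of named reads is above many of the shares given below. The question the design poses is which RNAs are attached to Seb1, a protein the series title ties to 3' end processing and the choice of polyadenylation sites, beyond those recovered without a tag. RNAs whose S. pombe and S. cerevisiae sequences are close would be favoured in such files, which was not tested. The values describe mostly rRNA, U2 and short matches.

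Ribosomal RNA dominated every library, and its make-up differed between Seb1-HTP and the controls. Reads naming the 35S rDNA were 89.7% and 95.1% of named reads in the controls and 83.4% and 76.8% in the Seb1-HTP libraries. Within them, 25S rRNA of the large ribosomal subunit made up 91.7% ± 2.79 (SD, n = 2) of control reads and 49.5% ± 1.57 of Seb1-HTP reads. The 5.8S rRNA, also of the large subunit, stood at 5.16% ± 0.858 in the controls and 28.3% ± 1.72 with Seb1-HTP, a 5.48-fold higher mean share. The 18S rRNA of the small subunit stood at 3.11% ± 1.90 and 22.1% ± 0.0744, a 7.12-fold higher mean share. Each of these 3 differences was larger than the spread between replicates and separated both Seb1-HTP libraries from both controls (exact permutation p = 0.333, the smallest possible). They are not separate results, since the 3 shares make up nearly all 35S rDNA reads. A pile-up of control reads in 25S lowers the 5.8S and 18S shares of the controls. The 5.8S rise, and the size of the 18S rise, therefore cannot be told apart from this effect. Shares without the piled-up 25S windows were not computed. Counted as distinct fragments, the 5.8S share was 1.98-fold and the 18S share 4.63-fold higher with Seb1-HTP.

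**Figure D1:**
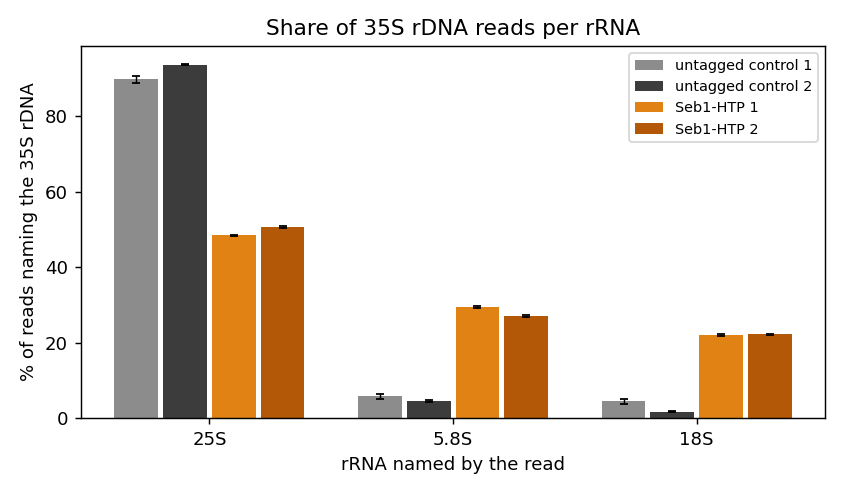
Percentage of reads naming the 35S rDNA (y axis) that name 25S, 5.8S or 18S rRNA (x axis), a bar per library, with 95% Wilson intervals. Both Seb1-HTP libraries lie near 49.5% for 25S, against 89.7% and 93.7% in the controls.

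Along the rDNA, 13 of 49 tested 250-nt windows were higher with Seb1-HTP and 5 were lower (edgeR quasi-likelihood test, adjusted p under 0.05). The 13 higher windows were 7 in 18S, 5 in 25S and 1 in 5.8S, and the 5 lower windows were in 25S. The totals used for scaling include the control reads piled up in these 5 lower windows. The pile-up lowers the control share of every other window. Smaller rises among the 13, such as that of 2.16 in 5.8S below, therefore cannot be told apart from this effect. Tests with totals that leave out the 5 windows were not run. The 25S window at XII 453500 to 453749 held 6.63% and 6.52% of named reads in the Seb1-HTP libraries and 0.240% and 0.280% in the controls (log2 fold change 4.65, SE 0.45, adjusted p = 0.00318 by edgeR). Its counterpart in the other rDNA copy, XII 462750 to 462999, rose by 4.99 on the log2 scale (SE 0.63). The 18S window at XII 456750 to 456999 rose by 5.89 (SE 0.67), from 0.0319% of control reads on average to 2.12%. The 5.8S window at XII 464500 to 464749 rose by 2.16 (SE 0.40) to 11.3%. The other 2 windows in 5.8S were not called. Of these, XII 455500 to 455749 in the first copy had a log2 fold change of 4.84 (SE 1.56, adjusted p = 0.0579 by edgeR). In the opposite direction, the 25S window at XII 462000 to 462249 held 24.1% and 28.4% of control reads and 0.735% and 1.60% of Seb1-HTP reads (log2 fold change -4.49, SE 0.56). The window at XII 453000 to 453249 of the first copy had a log2 fold change of -4.71 (SE 0.48). Profiles over the 49 windows correlated between the Seb1-HTP libraries (Pearson r = 0.984 across windows, which are not independent replicates) and between the controls (r = 0.973), while r between library kinds ran from -0.0624 to 0.00457. By ranks the kinds were less apart, with Spearman correlations of 0.920 between the Seb1-HTP libraries, 0.627 between the controls and 0.303 to 0.614 between kinds. The count of higher windows was 4 with distinct fragments, 34 without control 1, 7 without Seb1-HTP 1 and 7 without Seb1-HTP 2, whereas the same 5 lower windows were called under each of these.

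**Figure D2:**
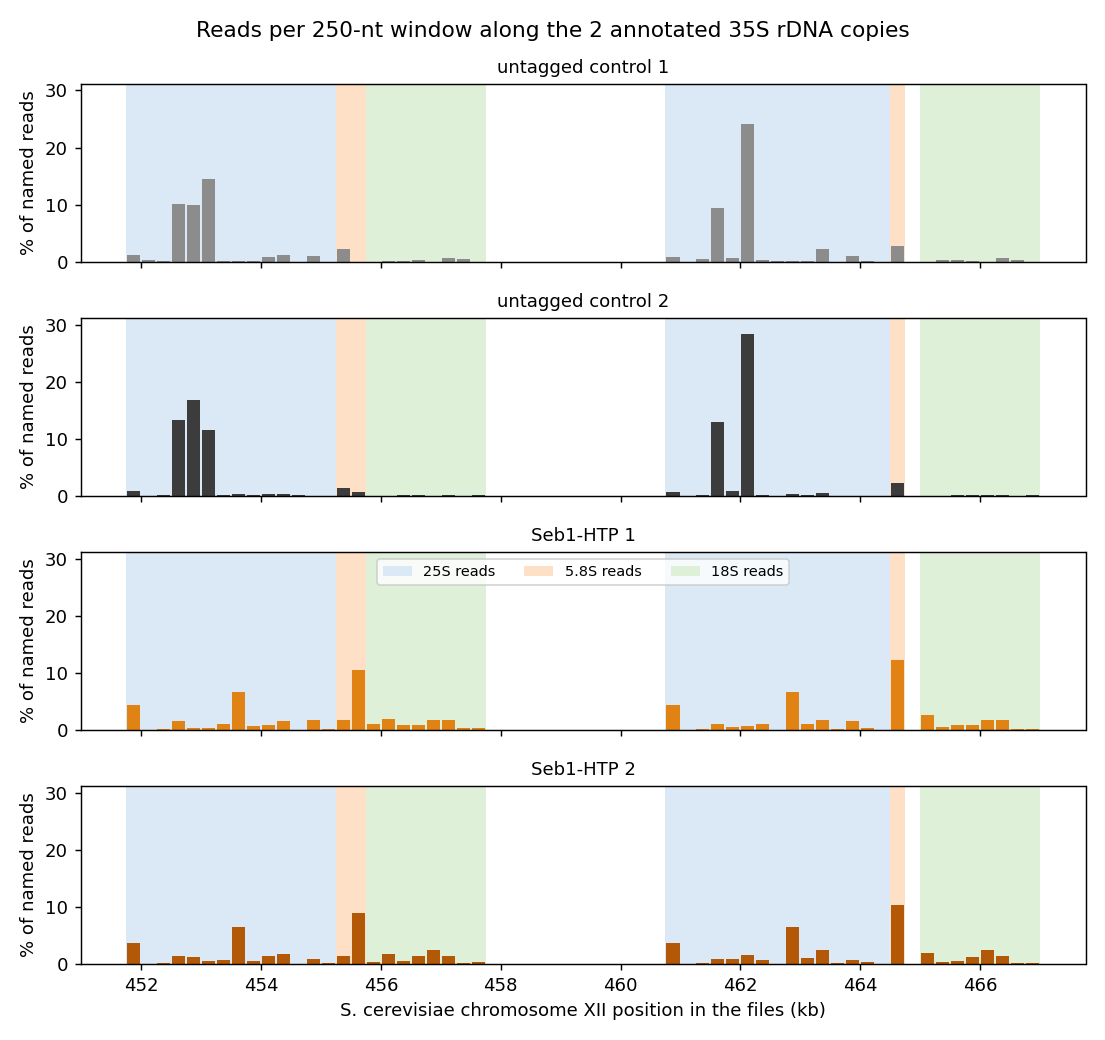
Percentage of named reads (y axis) in each tested 250-nt window along the 2 annotated 35S rDNA copies on S. cerevisiae chromosome XII (x axis, kb), a panel per library; shading marks the rRNA that most reads of the window name. Control reads pile up in a few 25S windows of each copy, and Seb1-HTP reads in the 5.8S windows and in 25S windows where the controls are near 0.

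U2 snRNA, the spliceosomal RNA that pairs with the intron branch site, was the non-coding feature with the highest mean RPM outside the rDNA with Seb1-HTP. Its feature LSR1 was named by 5134 reads (1.92%, 1.86 to 1.97) and 6260 reads (2.70%, 2.64 to 2.77) in Seb1-HTP libraries 1 and 2, by 3 reads in control 1 (0.0655%, 0.0223 to 0.192) and by 0 of 45339 reads in control 2, which allows a share of up to 0.00662%. The pooled ratio of shares was 379 (130 to 1840, exact interval of the counts), and 14.7 (5.00 to 71.5) in distinct fragments. Both rest on control 2, without which they were 34.8 (11.9 to 169) and 3.04 (1.03 to 14.8). The reads lay on the minus strand except for 5 of Seb1-HTP 2, and the single most frequent interval in both Seb1-HTP libraries was II 681795 to 681832, with 17.4% and 23.6% of the U2 reads. The difference was not called in the edgeR test of single-name reads (21221 ± 5677 RPM against 328 ± 463, SD, n = 2 each; log2 fold change 6.23, SE 2.60, adjusted p = 0.522). It was called by DESeq2, where reads were counted for each feature named (log2 fold change 6.40), and without control 1. Other snRNAs and stable RNAs were scarce: U1 (snR19) had 1 and 14 reads in the Seb1-HTP libraries, U4 (snR14) 0 and 6, U6 (snR6) 0 and 11, and the U3 snoRNA snR17a 3 and 59, each with 0 in the controls. U5 (snR7-L) had 1 and 40 reads with Seb1-HTP (0.000373% and 0.0173%, 0.0127 to 0.0235 in the second), 2 in control 1 (0.0437%, 0.0120 to 0.159) and 0 in control 2, with the highest share in control 1. The snRNA class as a whole was 2.13% ± 0.575 of named reads with Seb1-HTP and 0.0328% ± 0.0463 in the controls, a difference larger than the spread between replicates (exact permutation p = 0.333). In distinct fragments the class was 0.845% ± 0.180 with Seb1-HTP and 0.155% ± 0.219 in the controls.

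**Figure D3:**
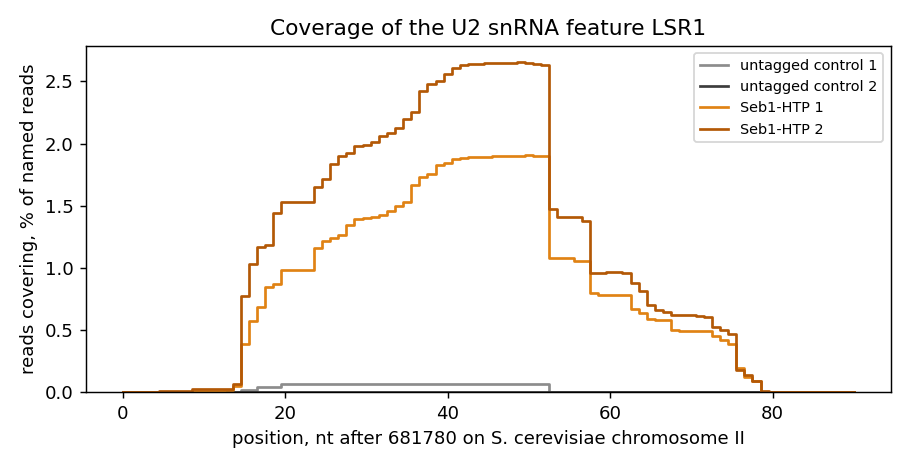
Reads covering each base in part of the U2 feature LSR1 as a percentage of named reads (y axis) against position on S. cerevisiae chromosome II (x axis, nt), a line per library. Both Seb1-HTP libraries peak over the same bases, with the 3 reads of control 1 on the same stretch and no line above 0 for control 2.

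For single features, no gene was called higher or lower with Seb1-HTP among 559 tested (0 and 0 by edgeR; 4 had an unadjusted p under 0.05, and DESeq2 called 1 and had 21 under 0.05). An unadjusted p under 0.05 was met by 124 with TMM factors and by 240 with the replicate block, again with 0 called. Of these 559, 438 had 0 reads in both controls. The 4 were LSR1 and AAH1 on the higher side and FIS1 and REF2 on the lower side; FIS1 and REF2 are named because of their p values, outside the rule, and their 49 and 8 control reads lay in control 1 alone. Leaving out Seb1-HTP 1 gave 93 higher features of 438 tested, leaving out control 1 gave 1, and counting reads for each feature named gave 7 higher and 3 lower of 1208. Those 10 included the rDNA features RDN25-1 and RDN25-2 on the lower side and RDN58-1, RDN58-2, RDN18-1, RDN18-2 and LSR1 on the higher side.

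Protein-coding features took 14.2% ± 0.874 of named reads with Seb1-HTP and 4.66% ± 1.25 in the controls, a difference larger than the spread between replicates (exact permutation p = 0.333). In reads, most of it (6.58 of 9.51 percentage points) came from RRT15 and YLR162W, a pair of small open reading frames at XII 489748 to 490545, which held 31325 and 14925 Seb1-HTP reads. Each of these reads lay on the strand opposite to the frame, so they are not mRNA of the pair. The pair was set apart here as rDNA-like. For YLR162W, the counts were 59 and 397 in the controls and 11691 and 8440 with Seb1-HTP. The large-subunit rRNA window at XII 451750 to 451999 held 53 and 397, and 11716 and 8644. The window at XII 460750 to 460999 of the other rDNA copy held 39 and 362, and 11683 and 8518. This close match goes with rRNA reads split among these places, which would then be missing from the rRNA shares above. For RRT15 the assumption was not tested. RRT15 reached 50624 ± 32003 RPM and YLR162W 40026 ± 5081 RPM with Seb1-HTP, against 14056 ± 12157 and 10821 ± 2919 in the controls. Neither passed the test, and their log2 fold changes turned below 0 with distinct fragments. With totals without rRNA and tRNA these log2 fold changes were 0.0438 and 0.405, against 1.85 and 1.89 in the test used. Without this pair, frames took 1.86% and 8.35% of Seb1-HTP reads and 3.71% and 0.642% of control reads, so the groups overlapped. In distinct fragments the groups did not overlap for these other frames, which took 18.98% and 30.3% with Seb1-HTP and 10.3% and 6.52% in the controls. For the pair they did overlap, at 4.27% and 2.19% against 3.21% and 3.91%. AAH1, which encodes adenine deaminase, had 157 and 1244 reads with Seb1-HTP and 0 and 1 in the controls; 99.4% of its Seb1-HTP reads fell in 1 stretch of 50 nt and 19.1% lay on the gene's own strand. DBP2, encoding an RNA helicase, had 153 and 296 reads against 1 and 0, PCL5 had 46 and 283 against 2 and 3, and ADA2, of the SAGA complex, had 16 and 268 against 0 and 0, at least 9.46-fold higher over the group floor of 3 reads. This limit was 19.2 without Seb1-HTP 1 and below 1 without Seb1-HTP 2 (0.993) or without control 2 (0.868). Of the Seb1-HTP reads of DBP2, PCL5 and ADA2, 76.2%, 98.2% and 99.6% fell in 1 stretch of 50 nt. On the gene's own strand lay 26.5%, 57.1% and 60.2%. None of these 6 frames passed the test (adjusted p from 0.522 to 0.652, edgeR).

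In the Seb1-HTP libraries, reads on open reading frames lay on both strands, and those on ribosomal protein frames mostly on the own strand. Long fragments on frames other than RRT15 and YLR162W leaned to the own strand in Seb1-HTP 2 only. As distinct fragments of 35 nt or more, these were 70.5% (69.0 to 71.9) of 4046 there and 44.0% (39.8 to 48.3) of 527 in Seb1-HTP 1. Leaving out RRT15 and YLR162W, 49.4% (48.0 to 50.8) of 4998 reads in Seb1-HTP 1 and 53.1% (52.4 to 53.8) of 19333 in Seb1-HTP 2 lay on the frame's own strand. Control 1 had 41.2% (34.1 to 48.7) of 170 reads and control 2 had 72.2% (66.8 to 77.0) of 291. For frames of ribosomal proteins, 79.0% (73.0 to 84.0) of 210 and 77.6% (74.4 to 80.5) of 713 Seb1-HTP reads were on the own strand, and among reads of 35 nt or more 98.9% (94.0 to 99.8) of 91 and 92.6% (89.7 to 94.8) of 421. These reads include repeats of the same fragments. Distinct fragments of 35 nt or more gave 96.3% (81.7 to 99.3) of 27 on 14 frames and 89.9% (85.6 to 93.0) of 257 on 81 frames. RPL9B alone gave 72 of the 210 reads of Seb1-HTP 1, each on its own strand. The control libraries held 1 and 13 reads on ribosomal protein frames, and 10 of the 13 in control 2 (76.9%, 49.7 to 91.8) lay on the own strand as well, with an interval that holds both Seb1-HTP values for all lengths.

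**Figure D4:**
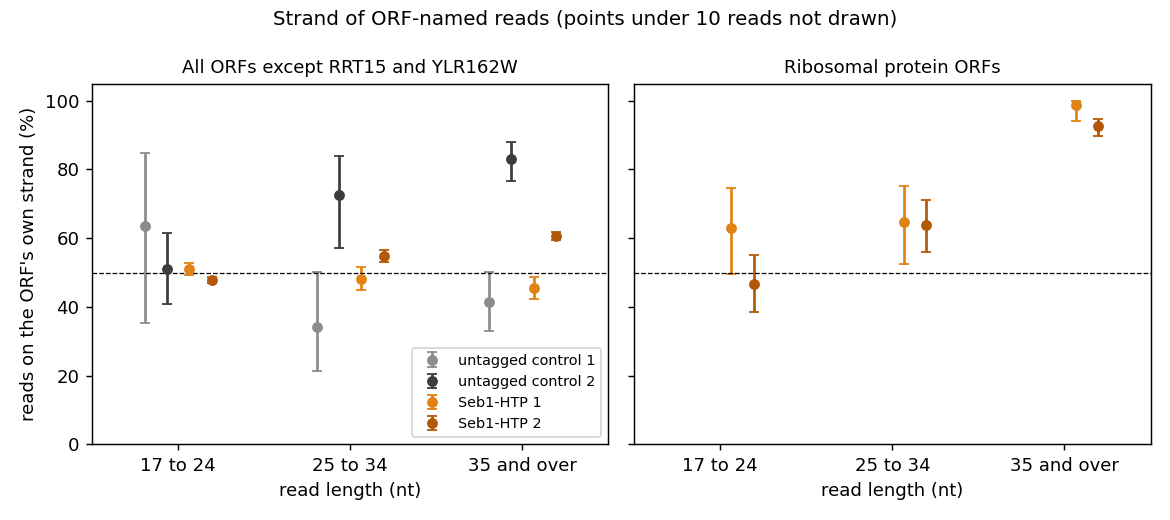
Percentage of reads on the open reading frame's own strand (y axis) by read length (x axis, nt) for frames other than RRT15 and YLR162W (left) and for ribosomal protein frames (right), points per library with 95% Wilson intervals. In Seb1-HTP libraries, reads of 35 nt or more lie above 90% on ribosomal protein frames and at 45.5% and 60.6% in the left panel, and ribosomal protein reads of 17 to 24 nt lie at 63.0% and 46.7%.

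Ribosomal protein frames held 783 and 3078 RPM in the Seb1-HTP libraries and 218 and 287 RPM in the controls. The value of control 1 is 1 read, below its floor of 655 RPM. Its interval, 0.00386% to 0.124% of named reads, holds the 0.0783% of Seb1-HTP 1. The totals also include the control reads piled up in the lower rDNA windows, which lowers both control values. Values without these windows were not computed, so these RPM values do not separate the groups. No member of the 13 tested passed the test, in all genes or adjusted over the list alone, and the list did not move against other genes (camera, adjusted p = 0.229). RPS4A had 10 and 161 reads against 0 in both controls, with each of its 171 Seb1-HTP reads on its own strand. Of these 171 reads, 94.7% fell in 1 stretch of 50 nt. RPL26B had 7 and 58 against 0. RPL9B, with 72 and 40 reads against 0, was at least 3.73-fold higher over the group floor, a limit that fell to 0.342 without control 2. Of the RPL9B reads with Seb1-HTP, 100% fell in 1 stretch of 50 nt.

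Transfer RNAs were the only list of the 5 tested that camera called, lower relative to other genes (36 tested of 209 matched; adjusted p = 3.74e-06), and the call was lost with an estimated correlation (adjusted p = 0.954). Its own median fitted log2 fold change was 1.45, of the opposite sign, and -0.53 with the 14 tRNAs at 0 in both controls set at their lower bounds. Features at 0 in both controls get large fitted rises. They were 14 of 36 tRNAs but 438 of 559 tested features, so the call can reflect which features the filter let in. Of the list's members, 0 were called in all genes or adjusted over the list alone. The tRNA share was 0.0280% and 0.749% in the Seb1-HTP libraries and 0.393% and 0.260% in the controls, so no direction was common to the replicates, and the list's call was lost without Seb1-HTP 1 (adjusted p = 0.192). The tRNAs tW(CCA)J, tI(UAU)L and SUP2 had 2 and 105, 10 and 27, and 0 and 18 Seb1-HTP reads, with 0 in the controls. Small nucleolar RNAs (9 tested, camera adjusted p = 0.312), chaperones (5 tested, adjusted p = 0.740) and features named as rRNA alone (4 tested, adjusted p = 0.902) were not called, and the rRNA list was called lower without Seb1-HTP 2 (adjusted p = 0.00235), but not with an estimated correlation there (adjusted p = 0.517) or with fry (0.637). The snoRNA snR190 had 10 and 209 reads with Seb1-HTP and 4 and 11 in the controls. For snR128, snR78 and snR81 these were 4 and 19, 0 and 19, and 0 and 19 against 0. The snR78 reads had a mean length of 20.9 nt. SSA1, HSP60 and STI1, which encode chaperones, had 3 and 41, 1 and 12, and 0 and 10 reads against 0. RDN5-1, RDN37-2 and RDN37-1 had 6 and 170, 13 and 109, and 10 and 59 against 1 and 5, 1 and 2, and 1 and 1.

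The remaining lists had under 3 tested members and no set test. Of the exosome, TRAMP and MTREC list, 2 of 10 matched names were tested. MTR4, encoding an RNA helicase of the nuclear exosome, had 30 and 26 reads with Seb1-HTP and 0 in the controls. CBC2 had 2 and 10, also with 0 in the controls. Of the MTR4 reads, 96.4% fell in 1 stretch of 50 nt and 42.9% lay on the own strand. The CBC2 reads had a mean length of 21.9 nt. Of 6 matched histone names, HHT1 was tested (0 and 11 reads). The mitochondrial list gave COX1 (7 and 36 reads) and 21S_rRNA (9 and 17), again with 0 in the controls. Mean lengths of these Seb1-HTP reads were 17.4 and 24.4 nt, where the shortest reads held are 17 nt. Reads this short need not stem from the feature named. The 10 matched names of 3' end processing and termination held 7 and 14 Seb1-HTP reads and 0 of them was tested, and the same was true of 7 glycolysis, 2 meiotic and 1 phosphate name. The lists of translation elongation, Pol II snRNAs and other stable RNAs matched 0 names. Among non-coding transcripts, XUT_12F-188 at XII 460187 to 460648, inside the rDNA, had 72 and 314 Seb1-HTP reads and 74 and 39 control reads (812 ± 769 RPM against 8510 ± 10819), and XUT_8R-242 had 17 and 98 against 0 and 1.

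Deletions, which UV cross-links can leave in cDNA, were more frequent in the controls. They are counted against the S. cerevisiae sequence, so a base that S. pombe lacks is recorded as a deletion too. These sources were not told apart. Reads with a deletion made up 44.0% (42.5 to 45.4) and 43.9% (43.5 to 44.4) of control reads and 12.7% (12.6 to 12.8) and 10.7% (10.6 to 10.9) of Seb1-HTP reads (exact permutation p = 0.333). In distinct fragments the shares were 22.7% and 22.1% in the controls and 9.69% and 7.82% with Seb1-HTP. In the controls deletions gathered at 1 site of 25S rRNA. At XII 453010, 85.2% and 73.3% of control reads over the base and 48.6% and 50.5% of Seb1-HTP reads had it deleted. The adjacent base XII 453011 was deleted in 65.7% and 54.1% of control reads over it and 37.7% and 38.9% of Seb1-HTP reads. For XII 453012 these were 65.9% and 54.0%, and 37.8% and 39.6%. Among reads away from this site and its counterpart at XII 462147, the shares were 10.5% and 5.32% in the controls and 12.3% and 9.76% with Seb1-HTP, so the direction turned and the groups overlapped. In 18S rRNA, 2.19% and 7.37% of control reads and 15.8% and 12.3% of Seb1-HTP reads had a deletion, whereas in 5.8S rRNA the shares were 36.7% and 12.99% in the controls and 9.96% and 12.9% with Seb1-HTP. Substitutions came to 4.92 ± 0.298 per 100 nt in the controls and 5.63 ± 0.202 with Seb1-HTP (SD, n = 2 each; exact permutation p = 0.333), counted against the S. cerevisiae sequence.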

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

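Counting distinct fragments was planned for features and RNA classes. The other tests in this part, and the bounds used to read all of them, were chosen after the results were seen. Reads that name no feature, which enter no comparison above, made up 2.12% and 4.90% of the reads of the Seb1-HTP libraries, above 1.61% and 0.334% in the controls. Of these Seb1-HTP reads, 49.3% and 33.9% came from 1 spot on the plus strand of S. cerevisiae chromosome XIII, with 2863 and 4040 Seb1-HTP reads (1.05% and 1.66%) and 0 in either control, where 0 of 45491 reads in control 2 allows up to 0.00659%. At this spot 87.2% and 99.5% of reads began at base 238752, and the median read lengths were 30 and 31 nt. The spot's reads came from 54 and 44 distinct fragments. Of them, 46.6% and 47.1% had no mismatch to S. cerevisiae. Among all reads of these 2 libraries it was 5.66% and 9.35%, at median lengths of 54 and 41 nt. The source of the spot was not tested.

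U2 reads were far more frequent in both Seb1-HTP libraries. A difference in depth is argued against: at the lower Seb1-HTP share, the controls together would have held 956 U2 reads and held 3, which is 0.314% of that number. Control 1 alone would have held 87.7 and held 3. Repeated fragments are argued against by the ratio of shares in distinct fragments, 14.7 with a lower bound of 5.00, although this bound was 1.03 without control 2. S. cerevisiae RNA as the source of the U2 reads is argued against by their mismatches to S. cerevisiae. Of U2 reads of 35 nt or more, at most 8.57% in a Seb1-HTP library had no mismatch. Other reads of the libraries are not covered by this test. A candidate explanation that stays open, as a hypothesis, is U2 bound by Seb1 or by proteins that come with it, and a binding partner was not tested.

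Open reading frames with reads on both strands point to a second pattern. Chance placement of other RNA on frames is one candidate explanation: 54.8% (50.3 to 59.3) of 465 tested frames had most Seb1-HTP reads on their own strand, which lies just above an even split and leaves this open. For ribosomal protein frames it is argued against, since 76.9% (68.0 to 84.0) of 104 had most reads on their own strand. These 104 are frames with any Seb1-HTP read, whereas the 465 passed the filter of 10 reads. Only 13 ribosomal protein frames passed that filter. Short reads alone cannot be told apart from other sources either: distinct fragments of 35 nt or more lay on the own strand for 44.0% in Seb1-HTP 1 but for 70.5% in Seb1-HTP 2. The biological explanation, conserved S. pombe mRNA for ribosomal proteins bound by Seb1, stays open and untested, because the controls held 1 and 13 such reads, of which 10 of the 13 in control 2 lay on the own strand too.

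Control 2 had the highest share of frame reads on the own strand, and long reads of Seb1-HTP 2 leaned the same way. Of reads of 35 nt or more with no mismatch, 84.0% (74.1 to 90.6) of 75 in control 2 and 64.5% (61.3 to 67.6) of 873 in Seb1-HTP 2 lay on the own strand. S. cerevisiae RNA or reads in control 2 cannot be told apart from other sources by strand, because reads of that length with a mismatch lay on the own strand about as often (74 of 90), a difference of 1.78 percentage points (-10.1 to 13.1). Transcripts of conserved S. pombe genes are argued against only for the reads with no mismatch and stay open for the others: 45.5% (38.0 to 53.1) of frame reads of that length in control 2 carried no mismatch, against 13.5% in Seb1-HTP 2 and at most 8.57% for U2 reads with Seb1-HTP. The design gives no biological difference between the controls, so no further explanation of that kind was tested.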

How the results depend on the processing

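The alternatives of strand, length, class order, crossed pairing, edgeR's camera, off-site deletions and limits with a library left out, and the shares of rRNA regions and tests in rDNA windows with all their alternatives, were chosen after seeing the data. The 0 calls in the gene test say little on stability, since simulated 64-fold changes at this spread were not recovered. Medians of fitted log2 fold changes were 4.94 in the test used, 4.72 with totals without rRNA and tRNA and 1.67 with DESeq2, and depend on genes with 0 control reads. DESeq2 gave no adjusted p for 520 of 559 features. Position and motif results were not run. The cause of the changes below was not tested.

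Higher features numbered 0, but 7 with reads counted for each feature named (3 lower), 1 with DESeq2, and 0 to 93 with a library left out (lower 0 to 0). The replicate number as a block gave 0 and 0 calls, and the crossed pairing 0 and 0, with a correlation of same-numbered deviations of -0.159; the numbers do not pair the libraries. With the replicate block, the rRNA list turned up (adjusted p = 0.926) and 16 rDNA windows were higher and 5 lower.

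The tRNA list lost its call with an estimated correlation (adjusted p = 0.954) and with fry (0.966), and lay between 1.71e-08 and 0.192 with a library left out. The rRNA list turned up with TMM (0.622) and with totals without rRNA and tRNA (0.942), and ranged from 0.00235 to 0.996 with a library left out. With camera on edgeR counts it was lower in each setting, called with totals without rRNA and tRNA (0.00821), with the replicate block (0.000566), without control 2 (0.0443) and without Seb1-HTP 2 (3.73e-05), and otherwise not (0.0833 with the libraries and totals used), and the tRNA list was called in each setting (at most 0.00145). At an estimated correlation, camera as used in the report did not call the rRNA list with totals without rRNA and tRNA or with the replicate block. It pointed up in both (adjusted p = 0.973 each). Chaperones and snoRNAs were called in no setting that tested them. With a library left out, camera as used in the report gave 0.894 to 0.967 for chaperones and 0.507 to 0.967 for snoRNAs, and both turned up without Seb1-HTP 1, at 0.967.

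Higher rDNA windows numbered 4 with distinct fragments and 7 to 34 with a library left out, lower ones 5 to 7. As differences in percentage points, Seb1-HTP minus control, distinct fragments gave -17.2 for reads naming several features (-11.3 in the values used), 15.9 for frames (9.51), 0.608 for ncRNA (-0.471), 0.690 for snRNA (2.09), 0.0943 for mitochondrial (0.0209), 0.0697 for other (0.0134), -35.1 for 25S (-42.2), 8.24 for 5.8S (23.1), 26.4 for 18S (19.02) and -13.7 for reads with a deletion (-32.2). Away from the 25S site, the deletion difference was 3.15. Counting reads for each feature named gave 6.73 for frames, 1.14 for snRNA and -8.13 for rRNA, and 1 class per record gave -12.2 for rRNA (0.0384). Reads of 35 to 55 nt gave -39.9 for 25S, 15.4 for 5.8S and 24.4 for 18S. With a library left out, mitochondrial differences ran from 0.0116 to 0.0302, and differences of both signs were met for ncRNA (-1.30 to 0.357), tRNA (-0.299 to 0.423), snoRNA (-0.0680 to 0.107) and rRNA alone (-0.0596 to 0.136).

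Among named genes, none of them called in the test used, LSR1 was called with DESeq2, with each feature counted and without control 1, and MTR4, snR128, snR78, snR81, tI(UAU)L, SUP2 and 21S_rRNA were called without Seb1-HTP 1. Log2 fold changes turned sign for RRT15 (-0.086) and YLR162W (-0.22) with distinct fragments, STI1 with DESeq2 (-0.026), snR190 with TMM (0.68), RDN5-1 with totals without rRNA and tRNA (-0.43), the block (-0.041) and the crossed block (-0.40), and RDN37-2 (-0.25, -0.21) and RDN37-1 (-0.66, -0.20) with totals without rRNA and tRNA and with each feature counted. With a library left out they turned at least once, over ranges of -0.28 to 3.38 for PCL5, -3.79 to 0.95 for snR190, -2.63 to 2.28 for RDN5-1, -0.83 to 2.54 for RDN37-2 and -0.58 to 2.69 for RDN37-1.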

Other observations

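The 4 libraries also differed in how often the same fragment was read. Reads per distinct fragment were 4.59 and 11.96 in the controls and 15.6 and 5.69 in the Seb1-HTP libraries, so the replicates of a group differed more than the groups. The Seb1-HTP libraries also differed from each other across features: 138 of the 559 tested features had 0 reads in Seb1-HTP 1 and 5 had 0 in Seb1-HTP 2, at similar named-read totals, and 503 had a higher RPM in Seb1-HTP 2. Reads on the mitochondrial chromosome numbered 110 and 285 with Seb1-HTP and 0 and 1 in the controls.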
